A study of Arabidopsis thaliana x Arabidopsis arenosa with 4 samples.

How the data were processed

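Poly(A) RNA from siliques of 3 interspecific F1 hybrids and of the allotetraploid Allo733 was sequenced with an Illumina library kit, per the labels' protocols, with 1 library for each of the 4 groups. The authors deposited RPKM values (reads scaled by transcript length and by the reads mapped in the library) per transcript, per the file headers, for each hybrid in total and for each allele, and RPKM of selected transcripts of each hybrid beside Allo733. The submitters' processing notes name the genome build TAIR 9. The mapping tool, the annotation, the way reads were assigned to alleles and the rule that selected the transcripts compared with Allo733 are not given in the sources used here. The letters T and A in the allele columns were read as A. thaliana and A. arenosa. RPKM divides by the library's own total, so a few abundant transcripts can shift all others, and any preference of the mapping for the A. thaliana reference would lower every A. arenosa share.

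The allele columns summed to the total within 0.000497% of it, except for 41 transcripts of the Col cross that had both alleles at 0 and were left out of allele comparisons. The allele table of the Col cross held 4 repeated header lines, which were dropped. Low values showed no steps of whole reads, so depth could not be recovered, and no counting interval or floor is given. Summed total RPKM was 710281 in the C24 cross, 762595 in the Ler cross and 754526 in the Col cross, over 19663, 20337 and 19889 transcripts. Isoforms of a gene had similar values (median ratio of the larger to the smaller of 1.09 over 2462 genes with 2 isoforms in the C24 cross), as when the same reads serve each isoform, so 1 transcript per gene was kept, the one listed in most crosses and then with the highest mean. Gene codes were matched to a TAIR10.1 annotation for names only, with no coordinates used; 16522 of 16610 codes matched, and genes without a symbol are given by code.

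The A. arenosa share is its RPKM over the sum of both alleles. Genes were called A. arenosa-predominant at 80% or more and A. thaliana-predominant at 20% or less, with a minimum total of 1 RPKM, which removed no gene. Ratios were taken as log2 of values plus a pseudocount of 0.1 RPKM, which understates changes of low genes. The only test with p-values was an intercept-only fit over the 3 crosses with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05; its spread holds ecotype and library together. Comparisons between crosses and with Allo733 used rules of size: 2 log2 units for allelic ratios between crosses, 2-fold after median centring for total expression and 2-fold against Allo733. Comparisons with Allo733 stayed within each deposited table. In 3 genes the value of a cross differed between its tables by more than 1%, among them AT5G42100, whose isoform values were exchanged; leaving these out was an added alternative.

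The 16 gene lists held 247 entries. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, where at least 3 genes were measured. For genes with high A. arenosa RPKM in the Col cross, medians have 95% intervals from 10000 bootstrap draws over genes, which hold no spread between libraries. Named genes followed a rule fixed before the data were examined. It took the 10 genes with the highest lowest share, the 5 with the lowest highest share and 3 per cross and direction for allelic ratio. All of these had at least 5 RPKM in every cross. It also took 3 per cross and direction for total expression and 10 per direction against Allo733. For these only the largest value had to reach 5 RPKM. All measured imprinted genes and up to 4 members of any other list were named too. Groups of genes were compared in total expression, and secondary wall and aliphatic glucosinolate lists were added, after the data were seen.

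The limma fit was tested on simulated data for 14660 genes, with 200 genes shifted. It recovered 0% of shifts of 1 log2 unit, 8% of 2, 70% of 3 and 88% of 4, with 0 false calls. With so few genes shifted, the adjustment is stricter than in the real fit, where 5073 genes had an unadjusted p below 0.05 by limma. The real fit called smaller departures, such as NRPD1A at 1.39 and CHR1 at 1.90 log2 units, so these recoveries do not describe it. In tests of the list percentile on 100 random lists of 12 genes, 6% fell outside the central 95%. Alternatives were a pseudocount of 1, a filter of 5 RPKM, no filter, a share threshold of 90%, rescaled shares, no centring, a 4-fold rule and leaving out each cross; all listed transcripts and a share of 50% were added later. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.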

Results

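RNA was measured in siliques, the developing fruits with their seeds, collected 4 days after pollination. The samples were F1 hybrids between tetraploid Arabidopsis thaliana and tetraploid Arabidopsis arenosa, with A. thaliana from the ecotype C24, Ler or Col, and Allo733, an allotetraploid line in generation F8. Each of the 4 groups held 1 library, so no difference between 2 groups has a replicate check. The series title asks about paternal gene expression in aborting hybrid seed. A. arenosa is taken here as the pollen parent because it is named last in each cross, although the labels do not state the direction. For each cross the deposited table gave RPKM per transcript in total and for the A. thaliana and A. arenosa alleles. It listed 15477 genes in the C24 cross, 15935 in the Ler cross and 15612 in the Col cross, of which 14687 were listed in all 3. No table listed a transcript with a total below 2 RPKM, no organelle gene was listed, and the read depth behind the values is unknown.

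The first question was how much of the silique RNA came from A. arenosa. Nearly all of it carried the A. thaliana allele. A. arenosa supplied 6.26% of summed RPKM in the C24 cross, 4.67% in the Ler cross and 6.62% in the Col cross (5.85% ± 1.04, SD, n = 3 crosses). For the median gene the share was 5.45%, 3.87% and 4.92% in the same order. Siliques consist largely of tissue of the seed parent, such as the fruit wall and the seed coats. RBCS1A, a small subunit of Rubisco, had an A. arenosa share of 1.16%, 0.965% and 0.912% in the C24, Ler and Col crosses, whereas the chlorophyll-binding protein gene CAB1 had 13.5%, 9.05% and 12.9%. CAB1 has close paralogs, so its reads are uncertain.

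**Figure D1:**
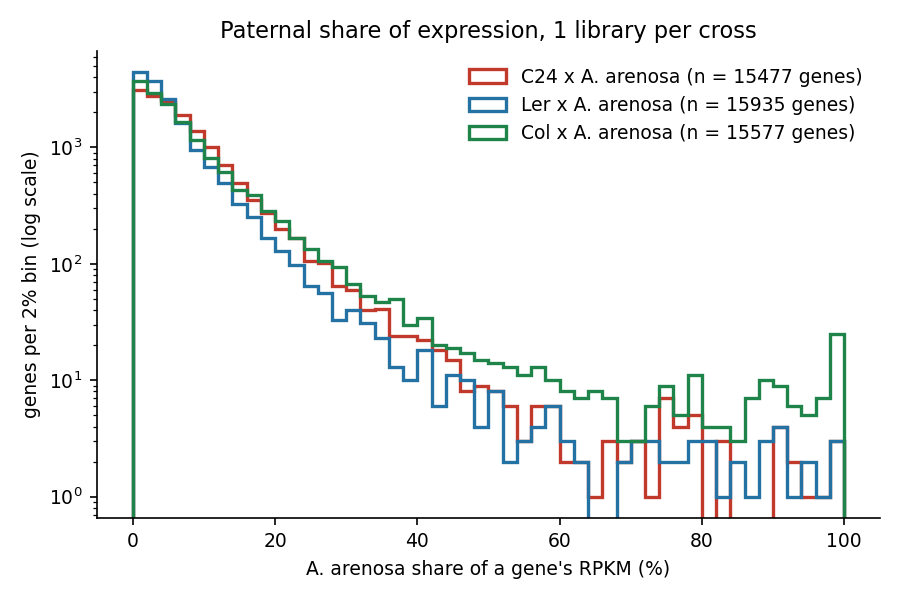
Number of genes (log scale) by the A. arenosa share of their RPKM in bins of 2%, 1 line per cross. Most genes lie near the medians of 5.45% (C24), 3.87% (Ler) and 4.92% (Col), and the Col line has the most genes above 50%.

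Genes expressed mostly from the A. arenosa allele were few, and the Col cross had the most. An A. arenosa share of at least 80% was found for 14 genes in the C24 cross, 21 in the Ler cross and 80 in the Col cross, whereas a share of at most 20% was found for 14506, 15325 and 14283 genes. Only the allele table of the Col cross held repeated header lines (4) and transcripts with both alleles at 0 (41). Among genes with allele values in all 3 crosses, 5 passed 80% in every cross, 9 in exactly 2 and 47 in exactly 1, where independent lists would share 4.02e-05 genes over the 3 crosses. The 5 genes were AGP23, an arabinogalactan protein gene, and AT1G10770, AT5G26717, AT5G50030 and AT5G60615; AT1G10770, AT5G26717 and AT5G50030 were named after their values were seen. A share of at most 20% in all 3 crosses was found for 12984 genes, against 12429 for independent lists. Over 14660 genes the shares had Spearman rank correlations of 0.48 to 0.55 between crosses. The lists were thus not independent, and neither number for independent lists is a chance level for the overlap.

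Of the 10 genes with the highest share in their lowest cross, AT5G60615 had 95.1% ± 4.32 A. arenosa RPKM and AGP23 92.3% ± 7.28 (SD, n = 3 crosses). VGD1, a pectin methylesterase gene needed for pollen tube growth, had 78.8% ± 3.22. It has a near-identical neighbour, VGDH1, with which it can share reads. The multicopper oxidase-like gene sks13 had 75.2% ± 5.25. The cytochrome P450 gene CYP78A5, which promotes organ growth, had 52.3% in the C24 cross, 55.1% in the Ler cross and 90.9% in the Col cross. The other genes of this group were AT5G45880 (67.8% ± 13.7), AT5G19580 (58.4% ± 7.26), AT2G18420 (73.8% ± 26.6), AT4G06477 (56.4% ± 12.4) and AT2G33220 (52.6% ± 13.8). At the other end the A. arenosa allele was listed at 0 in every cross for XCP2, a xylem cysteine peptidase gene, and for AT5G57040, AT4G38840, AT3G47295 and AT3G59778. A value listed at 0 can be a failed estimate, since 1415, 1829 and 1683 genes of the C24, Ler and Col crosses had A. arenosa values below 0.01 RPKM.

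**Figure D2:**
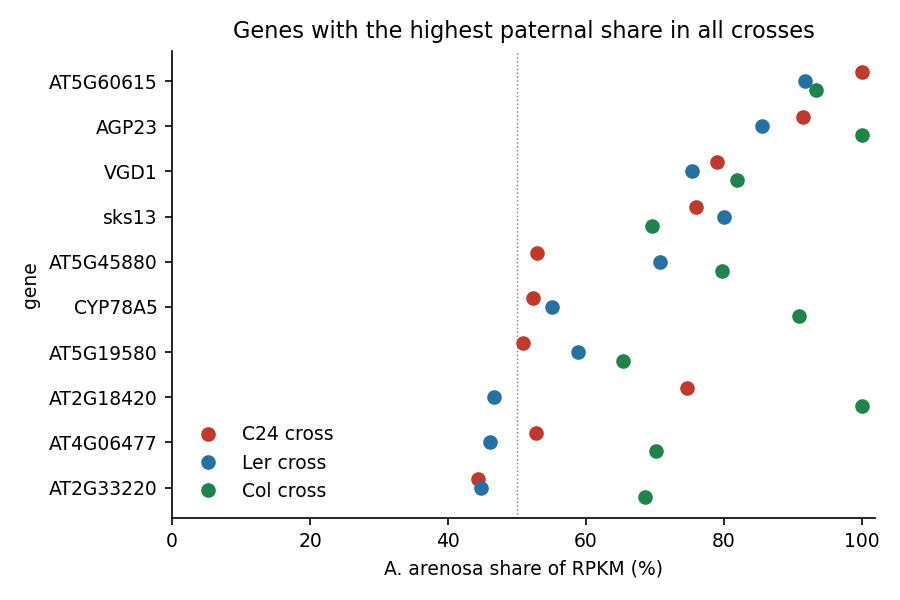
A. arenosa share of RPKM (%) of the 10 genes with the highest share in their lowest cross, 1 point per cross; the dotted line marks 50%. AT5G60615 and AGP23 lie above 80% in all crosses, and AT2G33220 spans the line.

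To ask which genes departed from the typical allelic ratio beyond the spread between crosses, the log2 ratio of A. arenosa to A. thaliana RPKM was centred on each cross's median and tested over the 3 crosses. VGD1 lay 5.95 ± 0.85 (SE) above the typical gene on the log2 scale and sks13 5.71 ± 0.79, both with an adjusted p of 0.0383 by limma and in 3 of 3 crosses. AT5G60615 and AGP23 did not pass, with adjusted p of 0.111 and 0.134 by limma, although their lowest shares over the crosses were 91.8% and 85.5%. Their log2 ratios varied more between crosses. The A. thaliana RPKM was near 0 for AT5G60615 in the C24 cross (0.000736) and for AGP23 in the Col cross (9.43e-06), where the pseudocount sets the ratio. XCP2 lay at -5.27 ± 0.64 (adjusted p = 0.0383 by limma). Its A. arenosa RPKM was listed at 0 in every cross, so this value and its spread come from the pseudocount, the A. thaliana RPKM and the centring. The same holds for any gene whose A. arenosa RPKM was listed at 0 in all crosses. By limma with Benjamini-Hochberg adjustment, 1168 of 14660 genes lay above the typical ratio and 493 below it. With the C24, Ler or Col cross left out, limma called 0 genes in either direction from the 2 libraries left, with 3758, 3481 and 4449 genes at an unadjusted p below 0.05, against 5073 with all 3. Without centring, which asks about equal alleles, 6 genes lay above and 14463 below, and with a pseudocount of 1 the counts were 3610 and 3502.

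The gene lists, fixed before the data were examined, placed the pollen list furthest from other genes. Of its 22 genes, 10 were listed in any cross and 8 were measured in all, so the values describe only this listed part. These 8 genes had a median A. arenosa share of 26.4% in the C24 cross, 24.1% in the Ler cross and 25.9% in the Col cross. The medians lay at the percentiles 100, 100 and 99.97 of 10000 random lists of matched expression. Median totals of the 8 genes were 3.98, 4.42 and 5.11 RPKM, not far above the lowest listed totals of 2 RPKM. Limma called 6 of the 8 above the typical ratio over all genes and 7 when adjusted over the list alone. VGDH1 had shares of 74.998%, 72.2% and 86.8% in the C24, Ler and Col crosses, and the plasma membrane proton pump gene HA8 had 21.04%, 18.8% and 30.4%. ANX1, a receptor kinase gene of the pollen tube, had 3.57%, 5.90% and 14.5%.

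Imprinted genes were seldom listed. Of the genes whose maternal copy is expressed in endosperm, HDG9 had A. arenosa shares of 16.5%, 28.4% and 0.0327% in the C24, Ler and Col crosses, and CDC48B had 7.63%, 0.000301% and 16.6%; limma called 0 of these, adjusted over all genes or adjusted over the list alone, and 0 had an unadjusted p below 0.05. Of those expressed from the paternal copy, VIM5, a methylcytosine-binding protein gene, had 46.9%, 51.5% and 88.4%, and the RNA polymerase IV gene NRPD1A had 10.2%, 8.52% and 12.5%; both lay above the typical ratio (2 calls over all genes and 2 adjusted over the list alone). Of the 20 type I MADS-box genes, 0 were listed in any cross. Of the endosperm and embryo regulators, IKU1 had 4.11%, 4.34% and 10.1%, HB-3 had 7.29%, 5.37% and 14.1%; limma called 0 by either adjustment and 0 had an unadjusted p below 0.05.

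Chromatin genes lay within the range of random lists. The 21 genes of DNA methylation had median shares of 8.42%, 5.62% and 7.32% (percentiles between 89.8 and 95.2), with 5 calls above and 1 below over all genes and 6 and 1 adjusted over the list alone. The 6 Polycomb genes had 6.50%, 6.06% and 6.86%, and VRN2, a Polycomb subunit gene, was the 1 call over all genes and adjusted over the list alone, with 20.08% in the C24 cross and 28.6% in the Col cross. The carpel list of 9 genes had 3.42% and 4.46% in the C24 and Ler crosses and 10.8% in the Col cross (percentiles 16.3, 77.7 and 99.4), where the MADS-box gene STK had 36.5% and SHP1 34.3%. The 12 flavonoid genes of the seed coat had 6.90%, 3.17% and 9.10% (percentiles 84.8, 43.3 and 98.5); the regulator TT8 had 26.5%, 31.4% and 68.1%. The 19 cell cycle genes had 9.57%, 6.24% and 7.17% (percentiles 98.9, 96.9 and 89.98), with 2 calls above over all genes and 6 adjusted over the list alone.

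The remaining lists fixed before the data were examined stayed within the central range of random lists in every cross. Photosynthesis (19 genes) had medians of 4.98%, 3.73% and 3.38%, defence (9 genes) 6.37%, 2.72% and 5.18%, the circadian clock (9 genes) 3.42%, 3.07% and 6.36%, senescence (4 genes) 6.43%, 5.52% and 13.2%, heat shock (3 genes) 5.13%, 5.56% and 2.58%, and the reference genes (12 genes) 6.36%, 3.99% and 4.74%, each in the order C24, Ler and Col. Limma calls in photosynthesis were 1 above and 6 below over all genes, and 2 and 7 adjusted over the list alone. Over all genes 3 reference genes lay above, 1 defence gene below and 1 carpel gene above, with the same numbers adjusted over the list alone; flavonoid genes had 1 call above and 1 below, and 2 and 2 adjusted over the list alone. Senescence had 0 calls by limma over all genes and 1 above adjusted over the list alone, with 3 genes at an unadjusted p below 0.05. Clock and heat shock genes had 0 calls by limma with either adjustment, with 2 and 1 genes at an unadjusted p below 0.05. Lists of secondary wall formation (24 genes) and aliphatic glucosinolate synthesis (7 genes) were drawn up after some members had been seen. In the same order of crosses, secondary wall genes had medians of 3.53%, 2.00% and 2.79% (percentiles 7.02, 1.4 and 4.27). Aliphatic glucosinolate genes had 1.91%, 1.498% and 2.32% (percentiles 2.13, 3.44 and 9.44). Only the wall median of the Ler cross and the glucosinolate median of the C24 cross lay below the central range of random lists.

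**Figure D3:**
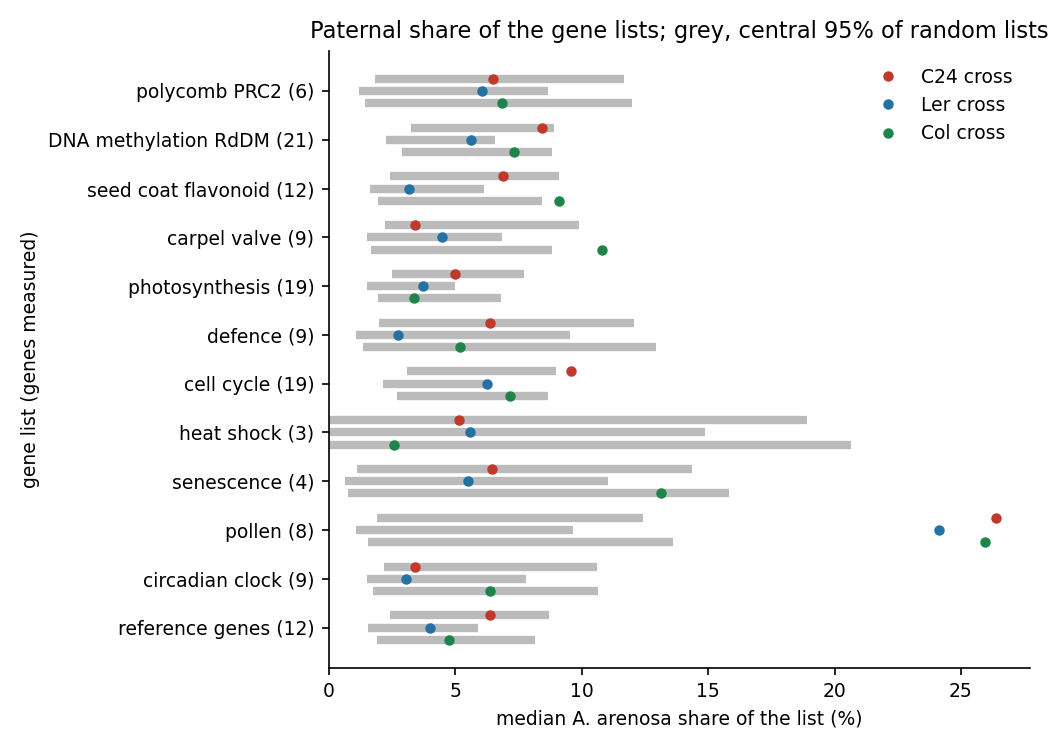
Median A. arenosa share (%) of each gene list with at least 3 measured genes, 1 point per cross, with the central 95% of 10000 random lists of matched expression in grey. The pollen list lies at 26.4%, 24.1% and 25.9%, right of its grey bars in all crosses.

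The next question was whether the crosses differed in allelic ratio. The Col cross had the most genes with a raised A. arenosa share, 496 at least 2 log2 units above both other crosses, against 359 in the C24 cross and 192 in the Ler cross. AT5G01870 carried 100% A. arenosa RPKM in the Col cross with 3.18% and 9.42% in the C24 and Ler crosses. The amino acid transporter gene UMAMIT15 carried 95.7% in the Col cross with 3.23% and 2.14% in the others, and for AT2G40980 the A. thaliana allele was listed at 0 in the Col cross. In the opposite direction AT1G13370 carried 90.4% and 91.2% in the C24 and Ler crosses and 6.08% in the Col cross, while for AT1G01250 and OEP6 the A. arenosa RPKM of the Col cross was near 0. AT2G19340 had 98.5% in the Ler cross with 12.2% in the C24 cross and 38.4% in the Col cross, and AT5G38980 had 31.7% in the Ler cross with near 0 in both others, as did AT5G21020 with 8.79%.

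For the C24 cross, ILL1 (27.7%), AT1G78170 (22.3%) and CCB3 (21.1%) had A. arenosa RPKM near 0 in both other crosses, and BT1, AT5G43260 and AT1G52910 were the reverse. ARPN, CYP77A6 and AT5G39730 had A. arenosa RPKM near 0 in the Ler cross alone. Ratios at least 2 log2 units below both others were counted for 363, 418 and 592 genes in the C24, Ler and Col crosses, but 264, 291 and 430 of these had A. arenosa values below 0.01 RPKM. With a pseudocount of 1 the counts above both others were 111, 20 and 150, and those below were 47, 45 and 61.

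A majority of A. arenosa RPKM in the Col cross alone was found for 115 genes, against 12 for the C24 cross alone and 9 for the Ler cross alone. This threshold of 50% was chosen after the data were seen, and the repeated header lines and missing allele values of the Col table apply here too. In the 115 genes the median share was 65.9% in the Col cross, 13.1% in the C24 cross and 9.61% in the Ler cross. The A. arenosa RPKM was higher than in the other crosses by a median of 2.60 on the log2 scale, the A. thaliana RPKM differed by -1.55, and the total differed by -0.03. In the 12 genes of the C24 cross the A. arenosa RPKM differed by 1.89, the A. thaliana RPKM by -0.96 and the total by -0.14, and in the 9 genes of the Ler cross by 0.57, -1.40 and -0.29. Choosing genes by their share itself favours low A. thaliana values in the cross.

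**Figure D4:**
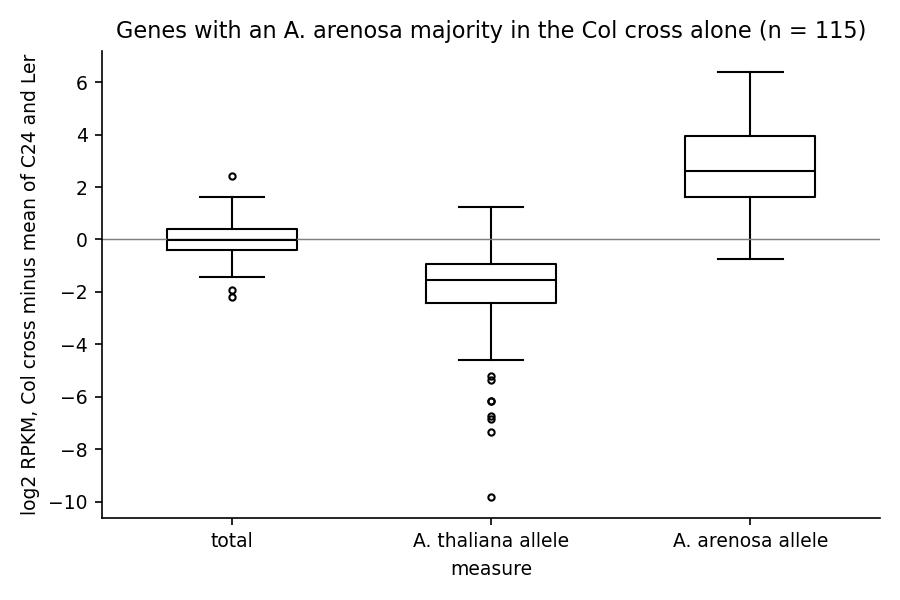
log2 RPKM in the Col cross minus the mean of the C24 and Ler crosses, for the 115 genes with an A. arenosa majority in the Col cross alone; boxes show quartiles, lines medians, whiskers values within 1.5 box heights, and circles the values beyond. Medians are -0.03 for the total, -1.55 for the A. thaliana allele and 2.60 for the A. arenosa allele.

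Total expression also differed between crosses, most often in the C24 cross, where 329 genes were at least 2-fold above both others and 147 below after centring. ESP, the epithiospecifier gene that directs glucosinolate breakdown, had 48.8 RPKM in the Col cross against 4874 in the C24 cross and 4150 in the Ler cross. TGG2, a myrosinase gene of the same defence system, had 2.91 RPKM in the Ler cross against 1182 in the C24 cross and 722 in the Col cross. FUM2, a fumarase gene, had 3.68 RPKM in the C24 cross against 30.0 and 48.2 in the Ler and Col crosses, the purple acid phosphatase gene PAP12 had 3.30 against 35.9 and 31.6, and the MADS-box gene AGL31 had 2.32 against 20.8 and 17.38. IQD10 had 49.6 RPKM in the C24 cross against 5.07 and 4.25 in the Ler and Col crosses, AT2G28315 had 133.1 against 12.8 and 13.0, and AT5G28450 had 45.0 against 3.96 and 4.11.

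In the Ler cross 161 genes were above and 196 below both others. PORA, a protochlorophyllide reductase gene, had 60.2 RPKM there against 2.94 in the C24 cross and 5.15 in the Col cross, AT2G34655 had 103.4 against 3.21 and 8.52, and AT1G19550 had 76.5 against 5.29 and 2.68. The expansin gene EXPA10 had 2.36 RPKM in the Ler cross against 55.3 in the C24 cross and 43.0 in the Col cross, and the glucanase gene BG3 had 7.75 against 67.9 and 107.2. In the Col cross 79 genes were above and 143 below. FER1, a ferritin gene, had 198.6 RPKM there against 25.7 and 48.5 in the C24 and Ler crosses, TLP5 had 56.9 against 8.08 and 10.1, and AT1G25141 had 13.1 against 2.17 and 2.87. KIN1, a cold-responsive gene, had 5.43 RPKM in the Col cross against 90.6 and 119.0, and AT5G42530 had 4.11 against 36.7 and 69.4. The median gene of the C24 cross lay at -0.18 log2 units from that of the Ler cross, which centring removed. Without centring the balance turned in the C24 cross, with 236 genes above and 247 below, and in the Ler cross, with 234 and 145, while the Col cross had 92 and 122. With a pseudocount of 1, 93 genes in place of 147 lay below in the C24 cross.

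Gene groups also differed in total expression between crosses. Each cross was set against the others, so the values of a gene in the crosses depend on each other. Against the mean of the other crosses, after centring, the 19 cell cycle genes had a median of -0.54 in the C24 cross, -0.03 in the Ler cross and 0.60 in the Col cross on the log2 scale, with 1, 9 and 19 genes above 0; without centring the median of the Ler cross turned to 0.09. The median of the C24 cross lay at percentile 0 of 10000 random lists of matched expression and that of the Col cross at percentile 100. The cytokinesis syntaxin gene SYP111 (KNOLLE) had 5.71, 14.7 and 20.4 RPKM in the C24, Ler and Col crosses, and the mitotic activator gene CDC20.1 had 6.74, 12.03 and 25.7. Genes of secondary wall formation, a list drawn up after some of its members had been seen, lay higher in the C24 cross. The 24 measured genes had medians of 2.40, -1.22 and -1.08, with 23, 0 and 3 genes above 0. Their median total was 83.5, 23.7 and 23.0 RPKM in the C24, Ler and Col crosses. The Ler and Col crosses were thus alike, and the negative medians of both follow from the high values of the C24 cross. The cellulose synthase gene CESA4 had 168.3 RPKM in the C24 cross against 23.9 and 20.9 in the Ler and Col crosses, and the laccase gene IRX12 (LAC4) had 350.9 against 40.9 and 42.8. Genes of aliphatic glucosinolate synthesis, likewise listed after 2 members had been seen, were higher in the Ler cross, with medians of -0.59, 1.01 and -0.43 over 7 genes. BCAT4, a branched-chain aminotransferase gene of this pathway, had 62.3 RPKM in the Ler cross against 7.15 and 2.25 in the C24 and Col crosses.

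**Figure D5:**
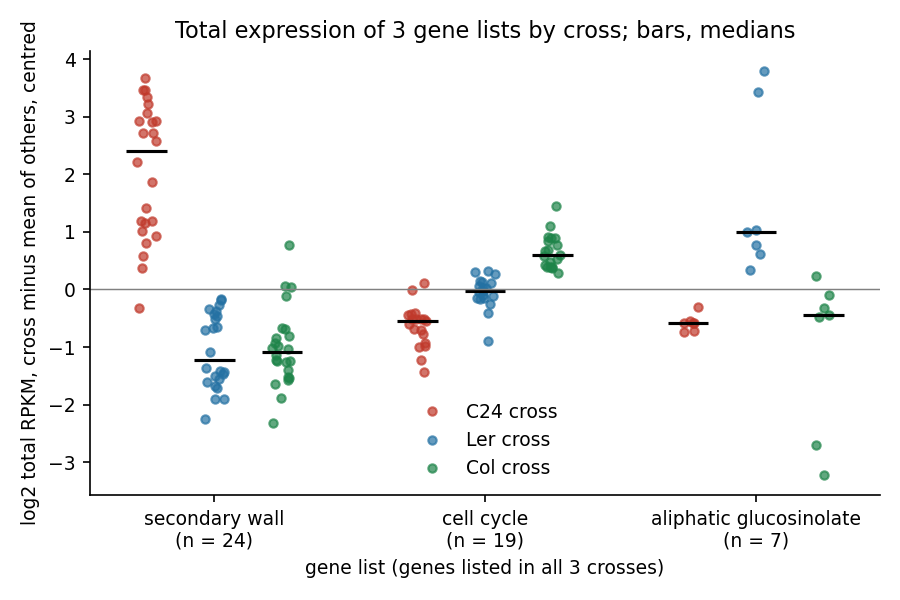
log2 total RPKM of a cross minus the mean of the other crosses, centred on the median gene, for the genes of 3 lists; points are genes and bars medians. Secondary wall genes have medians of 2.40 (C24), -1.22 (Ler) and -1.08 (Col), and cell cycle genes -0.54, -0.03 (0.09 without centring) and 0.60.

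The F1 hybrids were then set beside Allo733, an established allotetraploid. With A. arenosa as pollen parent, the fruit wall and seed coats of the F1 siliques come from the A. thaliana seed parent, whereas Allo733 carries both genomes. A difference from Allo733 can thus reflect the genomes of these tissues, which the design cannot separate. The 3 deposited tables hold transcripts the authors selected on these libraries by a rule not given in the sources used here, so the numbers describe those lists. Photosynthesis genes were listed higher in the F1 in nearly every case: 13 of 14 listed genes in the C24 cross, 16 of 16 in the Ler cross and 14 of 14 in the Col cross, with median log2 ratios of 0.68, 0.72 and 0.69. These medians lay at the 78.0, 75.3 and 88.4 percentiles of random lists drawn from the listed genes. CAB1 was at 1.23, 1.75 and 1.58 on the log2 scale in the C24, Ler and Col crosses, LHCB3 at 1.01, 1.08 and 1.01, and RBCS1A at 0.16, 0.30 and 0.06. LHCA3 was the exception, at -0.27 in the C24 cross. AGO4, which acts in RNA-directed DNA methylation, was at -1.08 in the C24 cross and -0.95 in the Col cross. Of the 12 reference genes, 5, 3 and 2 were listed in the C24, Ler and Col crosses, with medians of -0.35 in the C24 cross and -0.33 in the Ler cross; ACT8, an actin gene, was at 0.61 in the C24 cross and the polyubiquitin gene UBQ10 at 0.66 in the Col cross.

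By the 2-fold rule, 418 of 1320 listed genes were higher in the F1 than in Allo733 and 416 lower in the C24 cross, 239 and 226 of 807 in the Ler cross, and 250 and 227 of 783 in the Col cross. Among the largest differences, AGO3, an Argonaute gene, was higher in all 3 crosses (3.36 ± 0.21 on the log2 scale, SD, n = 3 crosses against 1 Allo733 library), as were the chlorophyll-binding protein gene LHCB2.3 (2.42 ± 0.12), the gibberellin-regulated gene GASA1 (2.09 ± 0.04), AT1G35290 (3.75 ± 1.39), AT1G06890 (2.96 ± 0.26), AT1G71690 (2.51 ± 0.22), AT1G67865 (2.99 ± 0.73) and AT4G15160 (3.21 ± 1.00). UGT88A1 had a transcript listed at 0 in Allo733 and at 30.5, 28.9 and 35.9 RPKM in the C24, Ler and Col crosses, and no fold is given. A transcript of the galactolipid synthase gene DGD1 was also listed at 0 in Allo733, with 12.3, 12.1 and 13.3 RPKM in the crosses. Lower in the F1 were the lipid transfer protein gene LTP2 (-3.71 ± 0.54), the triterpene synthase gene LUP2 (-3.11 ± 0.07), the stomatal patterning receptor gene ERL2 (-2.54 ± 0.30), AT1G27030 (-4.88 ± 0.74), AT1G73325 (-4.49 ± 1.08), AT5G61290 (-2.67 ± 0.09), AT1G75290 (-2.80 ± 0.27), AT4G12900 (-3.19 ± 0.98), AT5G18065 (-2.78 ± 0.41) and AT1G53070 (-2.79 ± 0.41).

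Of the 326 genes listed against Allo733 in all 3 crosses, 110 were higher in every cross, 171 lower in every cross and 45 mixed. By the 2-fold rule 53 genes were higher and 81 lower in all 3, where independent lists would share 0.096 and 0.0829. Because 1 Allo733 library serves all comparisons, unchanged groups simulated from the spread between crosses over all genes gave 118.2 higher and 127.3 lower genes shared by 3 crosses, more than observed. The simulated genes were not selected as the listed ones were, so neither number measures a shared change.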

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

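Of the tests in this part, those of scaling, of the Col cross and of the pollen list were chosen after the results were seen; that of the secondary wall genes not yet seen was set beforehand. Some genes and lists lay on opposite sides of Allo733 in different crosses, and with 1 library per cross none of these differences was tested. Of the genes listed against Allo733 in all 3 crosses, 45 went in opposite directions, 14 of them at least 2-fold in each cross. Secondary wall genes had median log2 ratios to Allo733 of 1.67 in the C24 cross (18 listed genes), -1.19 in the Ler cross (11 listed genes) and -1.16 in the Col cross (10 listed genes), at the percentiles 100, 5.89 and 7.41 of random lists drawn from the listed genes. Aliphatic glucosinolate genes had medians of -1.95 in the C24 cross (4 listed genes), 1.23 in the Ler cross (3 listed genes) and -3.21 in the Col cross (3 listed genes), at the percentiles 4.03, 79.4 and 1.2. Of these 6 medians, only that of the wall genes in the C24 cross and that of the glucosinolate genes in the Col cross lay outside the central 95% of random lists. ESP was at 1.38, 1.15 and -5.26 in the C24, Ler and Col crosses, and TGG2 at 4.32, -4.29 and 3.61. An isoform of the ribosomal protein gene RPS5A was at -3.58, 2.92 and -2.68.

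In the C24 cross secondary wall genes were higher and cell cycle genes lower than in the other crosses. A difference in library scaling would move both lists alike, but their medians lay 1.97 log2 units apart on opposite sides of the median gene, taking only the wall genes not seen beforehand. Those 19 genes had a median of 1.42 in the C24 cross, above all 10000 random lists, with 18 of 19 above 0, so the pattern was not limited to the genes first seen. Siliques further along in wall maturation, the ecotype, and differences between single plants or harvests would each give this value, which favours none of them, and all stay open.

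The 115 genes with more A. arenosa than A. thaliana RPKM in the Col cross alone exceed the 12 and 9 of the C24 and Ler crosses, a difference that was not tested. Choosing genes by their share favours low A. thaliana values, so added A. arenosa transcripts or tissue were tested on the 49 genes, 38 of them among the 115, whose A. arenosa RPKM in the Col cross reached the mean A. thaliana RPKM of the others, where A. arenosa held no majority. Addition as the whole source would change their log2 A. thaliana RPKM to no less than -0.0988. That is the dilution if all A. arenosa RPKM of the Col cross were added. The median was -0.99 (95% bootstrap interval over genes -1.60 to -0.20, with 32 of 49 below 0). Genes chosen likewise had 2.33 in the C24 cross (15 genes, 2 with a majority there alone) and 1.47 in the Ler cross (12 genes, 2 likewise). The allele columns sum to the total, so an error in their split that raises A. arenosa RPKM lowers A. thaliana RPKM. Choosing by A. arenosa RPKM does not remove such an error, so the fall counts against addition alone only where the split is right. The total of the 49 genes was higher by 0.71 (interval 0.38 to 1.03), against 2.26 and 1.56 in the genes chosen likewise in the C24 and Ler crosses. A choice by high A. arenosa RPKM itself favours a high total, so the total decides nothing. Addition as a part of the source, or together with an error in the split, stays open. For the other 77 genes it stays open as the whole. Their medians of -1.61 for A. thaliana RPKM and -0.25 for the total (interval -0.41 to -0.13) come in part from the choice. RNA counted for the other allele, as the Col table's repeated header lines and missing allele values might go with, stays open. A real exchange of allelic activity needs tissue with both genomes. With A. arenosa as pollen parent, fruit wall and seed coats carry only the A. thaliana genome. In the Col cross the median A. arenosa shares of the carpel and flavonoid lists lay at the percentiles 99.4 and 98.5, but the tissue behind this RNA was not measured. An exchange in tissue with both genomes and the ecotype stay open too. The A. thaliana RPKM lost was 0.984 times the A. arenosa RPKM gained over the 115 genes (interval 0.9 to 1.07), which miscounting and exchange would both give. The totals of the 49 and of the 77 genes differed in opposite directions, but splitting genes by A. arenosa RPKM itself pushes these totals apart.

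Pollen genes had a high A. arenosa share in all 3 crosses. Reads shared between VGD1 and VGDH1 cannot be the whole source, since without both the lowest percentile over the crosses was 99.82. RNA of A. arenosa pollen or pollen tubes within the siliques and expression of the paternal copies in the seed would both give a high share; the lowest percentile of the list, 99.97, is the pattern itself and favours neither, so both stay open. The list's most abundant gene, the tubulin gene TUA1, which is also expressed elsewhere, had 8.65%, 9.96% and 9.49% in the C24, Ler and Col crosses.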

How the results depend on the processing

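Of 226 recomputed values, 169 stayed within the set limits and 57 moved. A reversal of sign was looked for only in the medians of gene lists against Allo733, of which 0 reversed. The cause of a move was not tested unless the setting shows it. No filter moved nothing, since no listed total lies below 2 RPKM, so that setting tests nothing, and its 53 values count among the 169. All listed transcripts and leaving out genes that differ between the tables, both chosen after seeing the data, moved no count by over 1.5 times. Centring of the ratios to Allo733 was not run, since its tables hold selected transcripts. No paired analysis was possible because each group has 1 library. Depth is unknown, so what it limits cannot be stated. The share of the Col cross was 4.92% by the median gene. At a share threshold of 90%, A. arenosa-predominant genes numbered 11 in the Ler cross and 52 in the Col cross, with 5 in exactly 2 crosses and 3 in all 3; A. thaliana-predominant genes numbered 1395 in exactly 1 and 2835 in exactly 2. With a filter of 5 RPKM, which leaves fewer genes, A. arenosa-predominant genes numbered 5, 11 and 33 in the C24, Ler and Col crosses, and 21, 1 and 2 in exactly 1, 2 and 3 crosses; A. thaliana-predominant genes numbered 194 in exactly 1 and 755 in exactly 2. With each median share scaled to 50%, they were 1145, 1378 and 1737 for A. arenosa (1477, 573 and 303 in exactly 1, 2 and 3 crosses) and 2431, 2735 and 2752 for A. thaliana (2946 in exactly 1 and 527 in 3), because the midpoint moves. At a threshold of 50%, chosen after seeing the data, A. arenosa genes numbered 73, 64 and 208 (136 in exactly 1 and 26 in 3), and A. thaliana genes 13 in exactly 1 and 136 in exactly 2. With a pseudocount of 1, allelic ratios above both other crosses numbered 111, 20 and 150 and those below 47, 45 and 61 in the C24, Ler and Col crosses, and totals lower in the C24 cross numbered 93; without centring these numbered 247 against 236 above, which turned the balance, as it did in the Ler cross with 234 above and 145 below. Limma called 3610 genes above and 3502 below with a pseudocount of 1, and 6 and 14463 without centring. Leaving out each cross gave 0 to 0 calls in both directions, with 2 libraries left in the limma fit and 3481 to 4449 genes at an unadjusted p below 0.05. A 4-fold rule against Allo733 gave 144, 82 and 83 genes higher and 112, 68 and 92 lower, by its stricter size.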

Other observations

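The tests in this part were chosen after the first values had been seen, except that of the glucosinolate genes not yet seen, which was set beforehand. Other fixed lists also differed in total expression between crosses, each against the mean of the others on the log2 scale. Here too the values of the crosses depend on each other. The 4 measured senescence genes had medians of -0.50, 1.23 and -0.74 in the C24, Ler and Col crosses (percentiles 3.05, 100 and 0.46 of random lists), with NAP, a senescence transcription factor gene, at 5.69, 18.5 and 7.03 RPKM, while SAG13 was highest in the C24 cross at 18.204 RPKM against 2.40 and 3.64. The 21 DNA methylation genes had medians of -0.33, -0.01 and 0.22 (percentiles 0.19, 35.1 and 99.6); AGO9, an Argonaute gene active in ovules, had 18.7, 22.9 and 47.2 RPKM. The 12 flavonoid genes had 0.15, -0.34 and 0.11 (percentiles 87.7, 1.54 and 69.0), and the chalcone synthase gene TT4 had 1128, 757 and 1585 RPKM.

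The 9 clock genes had medians of -0.08, 0.39 and -0.35 in the C24, Ler and Col crosses (percentiles 31.9, 99.04 and 1.01). The evening gene TOC1 had 6.80, 11.9 and 7.26 RPKM and PRR7 had 34.0, 66.7 and 26.4, while the morning genes CCA1 and LHY were lowest in the Ler cross at 16.4 and 5.90 RPKM. The hour of collection is not in the labels. The pollen list had medians of -0.21, 0.05 and 0.16, photosynthesis 0.01, 0.06 and -0.09 (percentiles 70.8, 78.7 and 1.1), defence 0.04, 0.29 and -0.20, heat shock 0.05, -0.42 and 0.27, carpel genes -0.02, 0.04 and -0.03, Polycomb genes -0.10, 0.07 and 0.07, and reference genes -0.09, -0.09 and 0.22; of these, only the photosynthesis median of the Col cross lay outside the central 95% of random lists. Without centring, chosen as an alternative after seeing the data, the medians turned to -0.01 for flavonoid, -0.14 for photosynthesis, -0.11 for defence and -0.10 for heat shock genes in the C24 cross, to 0.11 for DNA methylation and 0.04 for reference genes in the Ler cross, and to 0.01 for carpel genes in the Col cross.

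A hypothesis was that the whole aliphatic glucosinolate pathway, not only BCAT4 and CYP83A1, was higher in the Ler cross. Of the 15 other genes on the list, 14 were listed in any cross but only 5 in all 3. These 5 genes had a median of 0.78 in the Ler cross, at percentile 99.97, and all 5 lay above 0. The values describe this listed part and not the whole pathway. SOT18 had 64.3 RPKM in the Ler cross against 25.1 and 33.2 in the C24 and Col crosses, and the regulator MYB28 had 18.5 against 9.80 and 9.91. With 1 library per ecotype the difference between crosses remains without a test.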
